A study of Mus musculus with 6 samples.

How the data were processed

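The assay was CUT&Tag for Arid3a, a DNA-binding transcription factor of the AT-rich interaction domain (ARID) family. In CUT&Tag an antibody directs a transposase to the protein on chromatin, and the DNA fragments cut around it are sequenced. The cells were primary mouse vascular smooth muscle cells (VSMCs), the contractile cells of the vessel wall. Per the labels, 3 libraries came from cells given a negative control siRNA and 3 from cells given an siRNA against Arid3a, each of the latter with its own siRNA number. The labels describe an angiotensin II model of abdominal aortic aneurysm in these cells but do not give the angiotensin II exposure of each library. They also do not say whether the libraries of a group came from separate cultures. The p-values of comparisons between groups of libraries thus measure only the spread between these libraries, which may be technical. Fisher's exact tests of the gene lists take genes as units and do not measure that spread.

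Per the submitters' processing notes, reads were aligned with Bowtie2 to mm10, Picard was used, and peaks were called with MACS2. Versions and options are not given in the sources used here. The files are 1 peak list per library, so peaks were called per library and not on pooled libraries. For each peak the authors deposited the interval, the summit position, an integer score, the fold enrichment at the summit over the local background of the same library (a ratio), and the −log10 of a p-value and of a q-value. The deposited score is the deposited −log10 q multiplied up and rounded. These per-peak values are the authors' own. Score and q-value were used only to describe, rank or filter peaks within 1 list. The fold and the p-value were also used to solve the summit fragments and background that are compared between libraries below. The lowest deposited −log10 q of the libraries lay between 1.30 and 1.32. In all 6 lists the peak names carry the name of the other group with the same replicate number. Groups were kept as the sample labels give them, and the libraries are called NC-labelled and siRNA-labelled for this reason.

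Total reads were not used here, so a proxy of depth was read from the peak caller's columns. With a pseudocount of 1, the fold at the summit and the −log10 p-value together fix a whole number of fragments at the summit and a local background, and both were solved for between 99.9% and 100.0% of the peaks of each list within a relative tolerance of 0.002. The most frequent lowest background of a list gives its background fragments per base. This was 0.670, 0.673 and 0.621 in NC-labelled libraries 1 to 3 and 0.475, 0.482 and 0.538 in siRNA-labelled libraries 1 to 3. The smallest peak width of a list, which the peak caller sets by default to the fragment length it estimated, was 228, 219 and 225 bp against 219, 195 and 202 bp. The background scales with depth times fragment length, so it is not depth alone. Divided by the smallest peak width, it was 2.94, 3.07 and 2.76 against 2.17, 2.47 and 2.66 fragments per kb. The median summit held 18 to 19 fragments in the NC-labelled and 16 in the siRNA-labelled libraries, so counting error is large at a typical peak. The solver was tested on 4694 simulated summits and returned the simulated fragments for 100% of them.

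Peaks of all 6 libraries were merged into union regions (overlap of at least 1 bp), and a library had a region if at least 1 bp of its peaks fell in it. The count of regions with a peak in 3 libraries of 1 group and none of the other was taken for the treatment split and for all 10 splits of the 6 libraries into trios. On simulated lists with 200 and 100 planted one-sided regions, 200 and 100 were found. Overlap between libraries was the Jaccard index (bp shared over bp in the union). Group means of peak number, covered length and shares were compared by a two-sided exact permutation test over the 20 assignments, whose smallest p is 0.1. Gene positions came from the RefSeq gene table of GRCm38.p6, the assembly of mm10, which gives each gene's start and end but was used without strand or exons. The planned promoter windows were therefore replaced by windows of 1000 bp either side of both ends of each of 21887 protein-coding genes, called gene ends below, and a peak at a gene end may lie at the start or at the end of transcription. The planned search for 15 motifs was not made because no genome sequence was used here. All 350 genes of the 18 gene lists matched the table. List members among one-sided genes were tested with Fisher's exact test against protein-coding genes with a gene-end peak in at least 1 library, with Benjamini-Hochberg adjustment over 36 tests.

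The named genes follow a rule fixed before the data were examined: Arid3a itself; the 10 genes of each one-sided set with the highest value of the smallest within-library percentile of −log10 q; the 5 highest genes with a peak in all 6 libraries; up to 4 members of each list whose number of libraries differs most between groups; and the 5 highest regions of each set away from gene ends. A few items that this rule selects are not reported here. The lists, the stricter threshold, the equal number of peaks, the wider windows, the other region rules, pairing by replicate number and leaving out each library were also fixed then.

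Agreement of each library pair with counting noise was measured as the mean chi-square per region of the summit fragments, over 4104 regions with a mean of at least 60 fragments. A value of 1 is counting noise for independent counts. Summits are maxima over a region, which vary less than single counts, so values under 1 do not show agreement closer than chance. Nor do they show that a pair differs by noise only. A test chosen after seeing the data compared the summit fragments of the 29572 regions with a peak in all 6 libraries and whole summits in each, using limma on log2(fragments + 0.5) after scaling each library by its median log2 difference, with Benjamini-Hochberg adjustment at 0.05. A fold on this scale understates the change of low regions. With 200 of the 29572 regions changed in simulated counts, it recovered 13.5% at 1.5-fold, 67% at 2-fold and 90% at 3-fold, with 0, 5 and 4 false calls. The simulation held counting noise only. Versions were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, R 4.3.3 and limma 3.58.1.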

Results

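Chromatin occupancy of Arid3a was profiled by CUT&Tag in mouse VSMCs, in 3 libraries labelled negative control (NC-labelled) and 3 labelled with siRNAs 1, 2 and 3 against Arid3a (siRNA-labelled). Each library gave a list of 43834 to 51682 peaks on 21 chromosomes. The background coverage solved from the lists was 1.31 times higher on average in the NC-labelled libraries, and every NC-labelled library exceeded every siRNA-labelled library (exact permutation p = 0.1 for 3 against 3 libraries, the smallest this design allows). The group is thus confounded with coverage. The peak names inside every list belong to the other group, so every direction below holds for the sample labels and would turn if the peak names were right.

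At the 4104 regions with the highest summits, siRNA-labelled libraries 2 and 3 had a mean chi-square per region under 1 (0.765). Library 1 lay above 1 with library 2 (1.22) and with library 3 (1.15). Since summits vary less than single counts, a value under 1 does not show that a pair differed by noise only. As a precaution libraries 2 and 3 were counted as 1 sample in means and SDs, which leaves n = 2 for the siRNA-labelled group. The value of 0.765 does not show that they are 1 library: their labels name different siRNAs, and the 3 pairs of NC-labelled libraries had similar values (0.773 to 0.836). In the NC-labelled group no pair lay above 1, so there was no such pair to set the others against. Keeping these libraries as 3 is an assumption. Counted as 1 sample, they would leave no test between the groups. Pairs between the groups lay between 1.09 and 1.64. Over all 29572 regions tested every pair lay under 1, between groups (0.811 to 0.997) as well as siRNA-labelled library 1 with libraries 2 and 3 (0.823 and 0.813).

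The first question was whether Arid3a itself carried Arid3a peaks, and whether these were lower in the libraries labelled as knockdown. The Arid3a gene lies on chromosome 10 at 79927043 to 79955018 (mm10). A region over its left end, from 79926503 to 79927851, had a peak in all 6 libraries, with 35, 36 and 41 summit fragments in the NC-labelled and 19, 22 and 34 in the siRNA-labelled libraries. A region inside the gene, from 79934112 to 79934790, also had a peak in every library, with 75, 95 and 83 against 68, 82 and 90 fragments. A further region inside the gene, from 79936723 to 79937574, held 49, 68 and 60 against 41, 53 and 54 fragments. These fragments are not scaled for the lower coverage of the siRNA-labelled libraries, and none of the 3 regions passed the scaled summit fragment test. CUT&Tag gives the position of the protein and not the amount of Arid3a transcript, so these values do not check the knockdown.

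**Figure D1:**
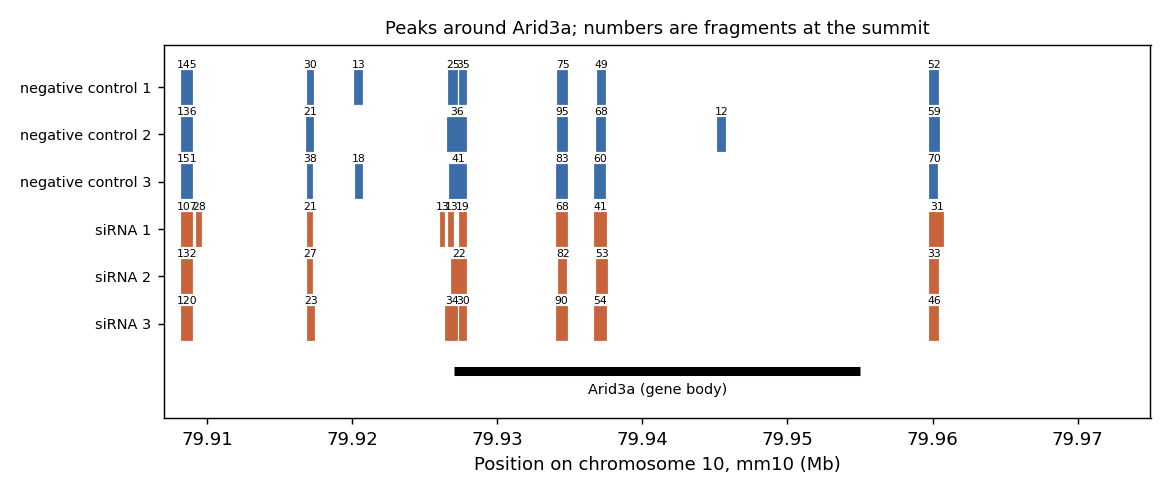
Peaks of the 6 libraries around Arid3a, with the position on chromosome 10 (mm10, Mb) on the x axis and 1 row per library (blue, NC-labelled; orange, siRNA-labelled); boxes are peak intervals and the numbers above them are fragments at the summit. The left end of the gene and 2 regions inside it carry peaks in every library, with 35, 36 and 41 against 19, 22 and 34 fragments at the left end.

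The second question was whether the Arid3a peak set shrank in the libraries labelled as knockdown. The number of deposited peaks did not separate the groups, at 49163 ± 1206 (SD, n = 3) in the NC-labelled and 47421 ± 5072 (SD, n = 2) in the siRNA-labelled libraries (exact permutation p = 0.7, and 1 with all 6 libraries apart, where the siRNA-labelled mean was 48616 ± 4196, SD, n = 3). Peaks covered 27.5 ± 0.171 Mb (SD, n = 3) against 23.5 ± 1.37 Mb (SD, n = 2), lower in every siRNA-labelled library (exact permutation p = 0.1 both ways of counting, the smallest possible; 23.8 ± 1.47 Mb with n = 3). Mean peak width was 560 ± 12.2 bp (SD, n = 3) against 497 ± 24.5 bp (SD, n = 2), with an exact permutation p of 0.1. Peaks at gene ends made up 22.6 ± 0.359% (SD, n = 3) against 23.2 ± 1.19% (SD, n = 2; exact permutation p = 0.6), peaks elsewhere in genes 40.9 ± 0.144% against 40.6 ± 0.850%, and the rest lay outside protein-coding genes. With only peaks of −log10 q of at least 5, the numbers were 36609 ± 1127 (SD, n = 3) against 33025 ± 3439 (SD, n = 2; exact permutation p = 0.1, and 0.2 with all 6 libraries apart), and the gene-end share was 1.24 points higher in the siRNA-labelled libraries (exact permutation p = 0.1 with all 6 apart, the smallest possible). Without siRNA-labelled library 1, the shortest list, the difference in peak number turned to 1844.5 more in the siRNA-labelled libraries and that in gene-end share to -0.284 percentage points.

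**Figure D2:**
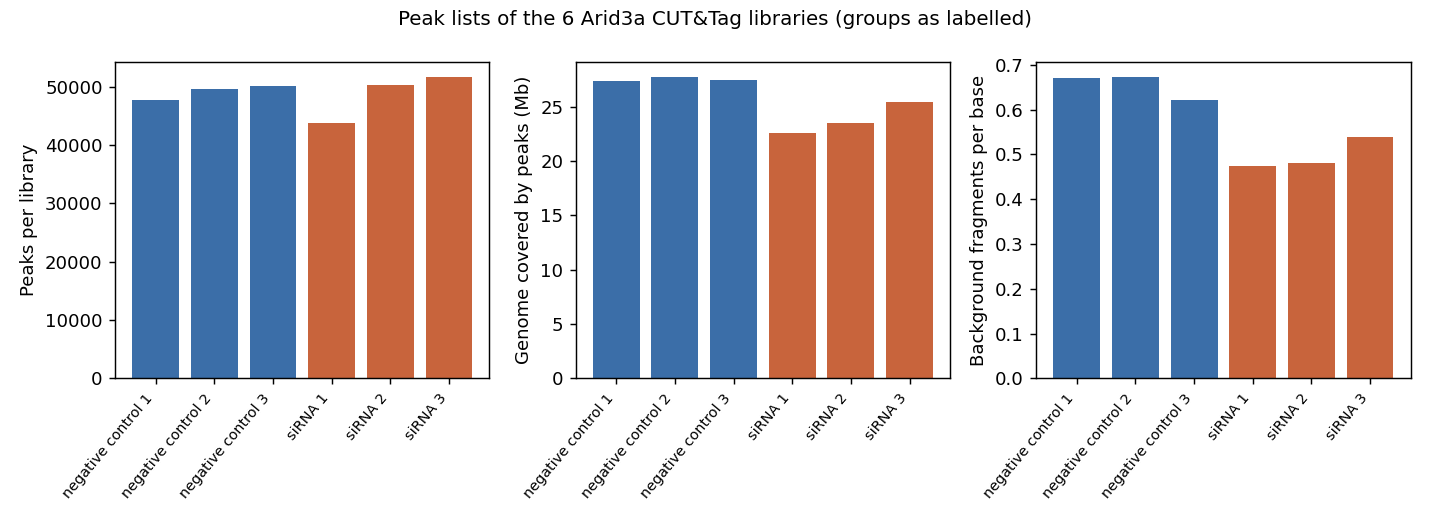
Bars give, for each library (blue, NC-labelled; orange, siRNA-labelled), the number of peaks, the genome covered by peaks in Mb and the background fragments per base. The 3 NC-labelled libraries lie above all siRNA-labelled libraries in covered length (27.4 to 27.7 against 22.5 to 25.4 Mb) and in background (0.621 to 0.673 against 0.475 to 0.538), but not in the number of peaks.

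The strongest peaks were shared by both groups. Of 9610 regions at or above percentile 75 of all 3 NC-labelled lists, 0 lacked a peak in every siRNA-labelled library. In the reverse direction it was 0 of 8938. No control library without the Arid3a antibody was analysed here, so these peaks are not shown to be Arid3a binding. Of 79295 union regions, 29602 (37.3%) had a peak in all 6 libraries and 23941 (30.2%) in 1 library only. At gene ends the highest-ranked shared peaks belonged to Lars2, the mitochondrial leucyl-tRNA synthetase (238 to 252 summit fragments over the 6 libraries), Hmgb2, a chromatin-associated high-mobility-group protein (326 to 364), Usp22, a histone deubiquitinase of the SAGA complex (335 to 353), Xpo1, the nuclear export receptor (372 to 396), and Ptp4a1, a protein tyrosine phosphatase (299 to 320). These fragments are not scaled for coverage, so similar counts do not show equal occupancy. Away from gene ends, regions among the highest-ranked lay inside Arrdc3 (chromosome 13, 80885382 to 80886471), Rab31 (chromosome 17, 65737352 to 65738311) and Aph1b (chromosome 9, 66795300 to 66796181), and 18328 bp from Wnt11 (chromosome 7, 98815561 to 98816755). The Jaccard index was 60.5% over the 3 NC-labelled pairs (59.9 to 61.4), 56.5% over the 3 siRNA-labelled pairs (56.1 to 57.0) and 56.8% over the 9 pairs between groups (55.7 to 58.4). Libraries of a group overlapped 1.70 percentage points more than libraries of different groups, against at most 0.199 in the other splits (one-sided exact permutation p = 0.1, the smallest possible). Without NC-labelled library 1, 2 or 3 it was 0.704, 0.749 or 0.659 points, and without siRNA-labelled library 1, 2 or 3 it was 2.63, 2.32 or 3.15. The excess came from the NC-labelled pairs, since the mean of the siRNA-labelled pairs lay under that of the pairs between groups.

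The third question was which regions had Arid3a peaks in 1 group only. A peak in all 3 NC-labelled and no siRNA-labelled library was found at 482 regions, 1.36% of the 35482 regions with a peak in every NC-labelled library. The reverse was found at 271 regions, 0.824% of 32908. The highest-ranked regions present in the NC-labelled libraries only lay 242284 bp from Tgfb2, a TGF-beta ligand (chromosome 1, 186379802 to 186380502), inside Rgs12, a regulator of G-protein signalling (chromosome 5, 35037281 to 35037823), inside Pla2g4a, the cytosolic phospholipase A2 that releases arachidonic acid (chromosome 1, 149855388 to 149855913), 109949 bp from Rps24 (chromosome 14, 24606910 to 24607233) and 16122 bp from Il1rn, the interleukin-1 receptor antagonist (chromosome 2, 24320125 to 24320737). Those in the siRNA-labelled libraries only lay inside Myom1, a sarcomere M-band protein (chromosome 17, 71070718 to 71071066), Rhof (chromosome 5, 123134554 to 123134818), Oca2 (chromosome 7, 56421847 to 56422277) and H6pd (chromosome 4, 150002112 to 150002517), and 9468 bp from Cobl, an actin nucleator (chromosome 11, 12474491 to 12474807).

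One-sided regions were weak in the lists that held them. Their median within-list percentile of −log10 q was 22.1 to 22.6 in the NC-labelled and 19.2 to 25.8 in the siRNA-labelled libraries. Of 19396 regions above percentile 50 of all 3 NC-labelled lists, 3 had no peak in the siRNA-labelled libraries, and of 18113 such regions in the siRNA-labelled lists, 3 had none in the NC-labelled libraries. The treatment split gave 753 one-sided regions in both directions together, and the 9 other splits gave 501 to 633. The excess of NC-only regions turned without siRNA-labelled library 1 (806 NC-only against 1087 siRNA-only), and after thinning to the same background coverage the counts were 350 and 348, with 46392 NC-labelled and 48190 siRNA-labelled peaks per list on average. With the same number of peaks in each list the excess stayed, at 407 NC-only against 240 siRNA-only regions.

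**Figure D3:**
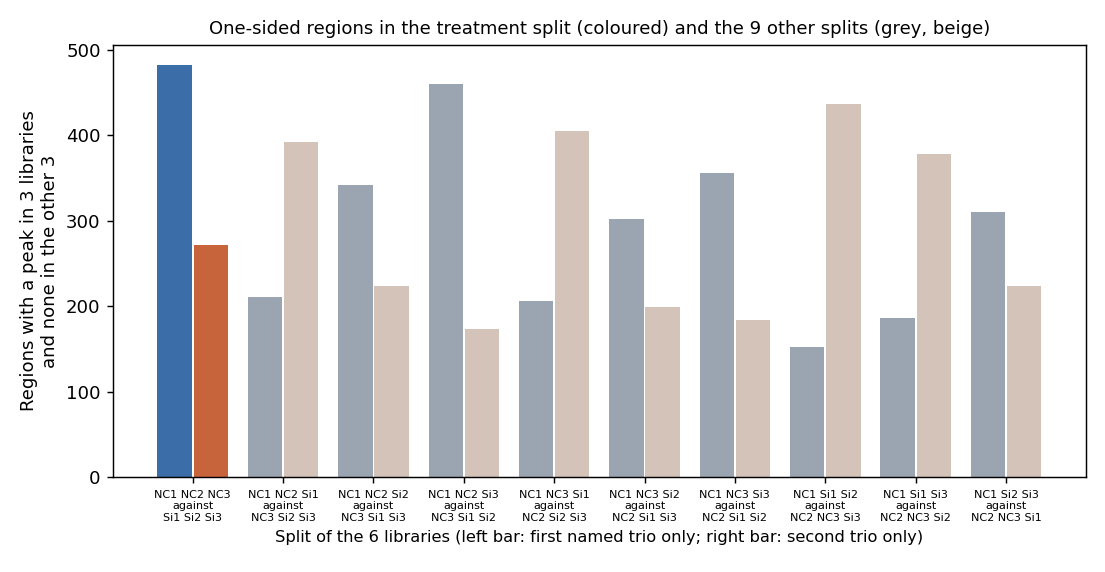
Bars give the number of regions with a peak in 3 libraries and none in the other 3, for the treatment split (blue, NC-labelled only; orange, siRNA-labelled only) and the 9 other splits of the 6 libraries (grey for the first trio named under the bars, beige for the second; NC and Si with a number name the libraries as labelled). The treatment split has 482 and 271 such regions, and the highest bar of the other splits is 460.

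Each siRNA library was also set against the NC-labelled background. Of the regions with a peak in 2 given NC-labelled libraries, the third NC-labelled library lacked 8.59% on average (7.63 to 9.21). The siRNA-labelled library 1 lacked 14.5% of the same regions (14.1 to 14.8), library 2 lacked 10.6% (10.3 to 10.7) and library 3 lacked 9.08% (8.82 to 9.35). On each of the 3 pairs every siRNA-labelled library lacked more than the held-out NC-labelled library, for library 3 by the least (9.35% against 9.21%, 8.82% against 7.63% and 9.06% against 8.92%). In the reverse direction the NC-labelled libraries lacked 6.52 to 9.81% of the regions of 2 given siRNA-labelled libraries. The held-out siRNA-labelled library lacked more than each of them when it was library 1 (14.1%) or library 2 (8.10%), and less than 2 of the 3 when it was library 3 (6.58%). Library 1 had both the lowest coverage and the fewest peaks.

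At gene ends, 9638 of 21887 protein-coding genes (44.0%) had a peak in all 6 libraries. A gene-end peak in every NC-labelled and no siRNA-labelled library was found at 37 genes. The highest-ranked were 9430038I01Rik (49 to 50 summit fragments), 9430069I07Rik (45 to 55), Pxk, a phox-domain kinase-like protein (18 to 25), Galnt18, a glycosyltransferase (13 to 25), Tk1, the cytosolic thymidine kinase of S phase (34 to 45), Micu2, a regulator of mitochondrial calcium uptake (11 to 13), Gm52875 (9 to 15), Tgfb1i1, which encodes the focal adhesion protein Hic-5 (14 to 19), Lrp8, a lipoprotein receptor (26 to 101), and Pcdhgc4 (17 to 19), a member of the protocadherin gamma cluster, whose genes share an end. For 8 of the 37, among them 9430038I01Rik, 9430069I07Rik and Lrp8, a siRNA-labelled library did have a peak in the same union region that stopped short of the gene-end window.

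The reverse was found at 20 genes. Among the highest-ranked were Tmem151a (31 to 42 summit fragments), Sh2b1, an adaptor of receptor tyrosine kinases (15 to 26), Ccdc50 (18 to 21), Shcbp1 (7 to 11), Tnfrsf21, the death receptor DR6 (7 to 13), Cd38, an ectoenzyme that consumes NAD (6 to 7), Pld6 (11 to 14), Nle1 (8 to 11) and Oas1e (7 to 10). For Sh2b1 an NC-labelled library had a peak in the same union region. The treatment split gave 57 one-sided genes and the other splits 33 to 49. The 57 include the genes with a peak of the other group in the same union region (8 NC-only and 1 siRNA-only). Such genes were not counted for the other splits, so the comparison without them was not made. With 3 libraries against 3 no single gene or region can reach an exact p below 0.1, so these are lists of presence and not of significant change.

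The fixed gene lists asked whether programmes of smooth muscle and vessel disease differed between the groups. No member of any list had a one-sided gene-end peak (0 of 350 in each direction). With so few one-sided genes, 0.780 NC-only and 0.422 siRNA-only members were expected by chance over all lists together, so the 36 Fisher's exact tests gave p = 1 by construction (0 at an unadjusted p under 0.05) and do not tell whether the lists differ. Among 20 contractile smooth muscle genes, 12, 11 and 12 had a gene-end peak in the NC-labelled and 10, 11 and 10 in the siRNA-labelled libraries (exact permutation p = 0.2, adjusted p = 1 over the lists). Cnn1, the smooth muscle calponin, and Myocd, the cofactor of serum response factor that drives the contractile programme, each had a peak in 3 NC-labelled and 1 siRNA-labelled library. Acta2 and Tagln had a peak in every library. Of the matrix genes, Col3a1 had a peak in 3 against 1 library and Mgp in 2 against 1, Bgn and Eln each had one in 0 against 1, and 16, 18 and 16 against 18, 17 and 16 of the 22 members had one.

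Other members that differed by 2 libraries included the inflammatory caspase gene Casp4 (2 against 0), Thy1 (2 against 0), the interleukin-1 receptor gene Il1r1 (0 against 2), the endothelial transcription factor gene Erg (0 against 2) and the T cell receptor component gene Cd3d (0 against 2). Inflammation and NF-kB genes had peaks at 17, 19 and 18 against 19, 19 and 17 of 22 members, with Tnf in 1 against 0 libraries. Members of the angiotensin II and oxidative stress list had 12, 10 and 9 against 11, 10 and 10 of 21, with the angiotensin receptor gene Agtr1a in 1 against 2 libraries. Matrix-degrading proteases had 14, 16 and 15 against 15, 14 and 13 of 19, with Mmp13, Mmp14 and Timp2 each in 3 against 2 and Ctss in 0 against 1. Of the TGF-beta list, 14, 14 and 14 against 14, 13 and 15 of 18 had peaks. The cell cycle list had 24, 26 and 25 against 24, 25 and 25 of 26, p53 targets had 18 of 19 in every library, and the ARID and chromatin list had 24, 23 and 24 against 24, 24 and 23 of 24. Genes are not independent replicates, and in each of the 18 lists the counts of the groups overlapped (smallest exact permutation p = 0.2).

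**Figure D4:**
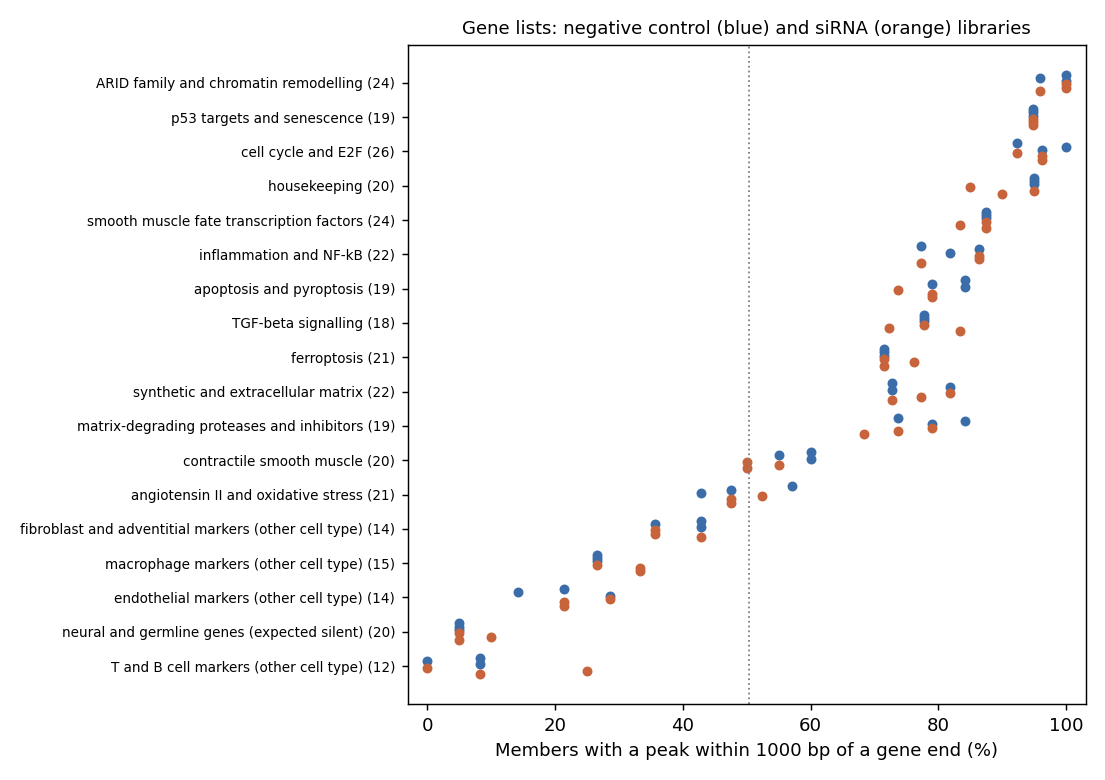
Points give, for each gene list (members in brackets), the share of members with a peak within 1000 bp of a gene end in each library, in % (blue, NC-labelled; orange, siRNA-labelled); the dotted line is the mean share of all protein-coding genes over the 6 libraries. The points of the groups overlap in every list, and the lists span from 0 of 12 T and B cell markers to 24 of 24 ARID and chromatin genes in single libraries.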

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

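The test of the peak names was chosen after the result was seen. In all 6 lists the peak names carry the library name of the other group with the same replicate number: the list of the library labelled negative control 1 holds names of siRNA 1, and so on through each pair. This column is outside the comparisons. A swap of the sample labels, a swap of the files at deposit or a swap of names at peak calling may have caused it. Whether these are mislabelled libraries was not decided by the number of files with such names (6 of 6), which fits a wrong label and a wrong peak name alike. A lower amount of Arid3a would be expected to lower the signal, and covered length was lower in the siRNA-labelled libraries. Coverage was lower there too, so this argument cannot be told apart from a coverage difference. The median fold of the peaks over their local background overlapped between the groups. It was 5.96, 6.01 and 5.81 in NC-labelled libraries 1 to 3 and 5.87, 5.98 and 5.88 in siRNA-labelled libraries 1 to 3. This median is taken over called peaks, which differ between the lists. If the peak names are right, every direction between the groups turns and every count of one-sided regions changes sides, while the regions and genes with a peak in all 6 libraries stay as they are.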

How the results depend on the processing

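Of 114 values under another setting, 72 kept their direction or stayed within 1.5 times, 40 moved (counts by more than 1.5 times, 1 share by more than its SD between libraries) and 2 reversed, both without siRNA-labelled library 1. Pairing by replicate number left peak number, covered length and gene-end share the same by construction. The excess of NC-only over siRNA-only regions was not scored itself. Its turn without siRNA-labelled library 1 (806 against 1087) was among the moved values, and its loss after thinning (350 against 348) among the kept. Leaving out each library gave a difference in peak number (siRNA-labelled minus NC-labelled) from -2079.5 to 1844.5, in gene-end share from -0.284 to 0.692 points, 806 to 1205 NC-only and 518 to 1087 siRNA-only regions, 63 to 106 NC-only and 37 to 62 siRNA-only genes, and 3 to 358 regions past the summit fragment test. One-sided counts rise by construction, since fewer libraries must agree. With −log10 q of at least 5, siRNA-only regions were 118 and genes 11, while NC-only regions rose to 548. The same threshold gave a difference of -2774 peaks and 1.24 points of gene-end share. Stricter peaks in the group that has them and no peak in the other left 54 NC-only and 24 siRNA-only regions, and 5 and 3 genes. With at least 50% of a region covered, NC-only regions were 1069, and with summit windows siRNA-only regions were 427; the cause was not tested. Pairing by replicate number (replicate block) gave exact sign-flip p = 1 for peak number, 0.25 for covered length (the smallest possible) and 1 for gene-end share, and 100 regions past the summit fragment test. Same-numbered libraries correlated at 0.041, 0.032 and -0.022 in their deviations from the group means, within the -0.075 to 0.048 of the other pairs. This gives no sign of pairing by number, but counting noise lowers such correlations, so pairing is not excluded. Chosen after seeing the data were thinning and a single p threshold (474 and 275 one-sided regions), the summit fragment test with its alternatives, and counting siRNA-labelled libraries 2 and 3 as 1 sample, which left 12 regions past that test. With the same number of peaks in each list, siRNA-labelled libraries 1, 2 and 3 lacked 8.05%, 7.24% and 6.64% of the regions of all NC-labelled libraries, in place of 10.5%, 7.22% and 5.91%, and with −log10 q of at least 5 they lacked 12.5%, 8.01% and 6.74%. The motif alternatives were not run. Depth limits what the one-sided regions show, since their median summit held 8 to 11 fragments.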

Other observations

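Chosen only after the peak lists were seen were the tests of the lists against all genes, the summit fragment test with its alternatives, thinning, the agreement of library pairs, the strength of one-sided regions and, as a test of chance, the counts over the 10 splits. The fixed gene lists differed far more from each other than between the groups. Compared with 44.0% of all protein-coding genes, a gene-end Arid3a peak in all 6 libraries was more frequent in 9 lists and less frequent in 3 (Fisher's exact test, adjusted p under 0.05 for 12 of 18 lists). It was found at 23 of 24 ARID and chromatin remodelling genes (adjusted p = 1.58e-06), 24 of 26 cell cycle and E2F genes (5.20e-06), 18 of 19 p53 targets and senescence genes (2.55e-05), 20 of 24 smooth muscle fate transcription factors (0.000487), 17 of 20 housekeeping genes (0.00105), 17 of 22 inflammation and NF-kB genes (0.00462), 14 of 19 apoptosis and pyroptosis genes (0.0213), 15 of 21 ferroptosis genes (0.0260) and 13 of 18 TGF-beta genes (0.0295). It was found at 2 of 14 endothelial markers (0.0444), 0 of 12 T and B cell markers (0.00462) and 1 of 20 neural and germline genes (0.000634).

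The contractile genes (9 of 20) and the angiotensin II list (9 of 21) lay close to the share of all genes (adjusted p = 1 for each). Matrix genes (14 of 22, adjusted p = 0.117), proteases (10 of 19, 0.592), macrophage markers (4 of 15, 0.260) and fibroblast markers (5 of 14, 0.675) did not pass. Genes are not independent, and no control library without the Arid3a antibody was analysed here, so these shares do not separate Arid3a binding from the general accessibility of active gene ends.

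Summit fragments of the shared regions differed between the groups at 56 of 29572 regions (limma, adjusted p under 0.05; 3339 at an unadjusted p under 0.05), 23 higher and 33 lower in the siRNA-labelled libraries. Lower regions lay inside Itih5 (chromosome 2, 10168006 to 10168832; 38, 35 and 27 against 13, 12 and 9 fragments, log2 fold −1.23, adjusted p = 0.00473), inside Zbtb11 (59, 60 and 62 against 21, 30 and 28, −0.91), at an end of Upf3a (60, 74 and 65 against 29, 24 and 37, −0.86), inside Arid5b, another ARID family gene (47, 48 and 36 against 14, 20 and 24, −0.89), 2854 bp from the chemokine gene Cxcl2 (27, 38 and 35 against 12, 13 and 17, −0.93), and 9108 bp from the matrix proteoglycan gene Lum (61, 53 and 70 against 26, 33 and 35, −0.67). Higher regions lay 18911 bp from Perp (chromosome 10, 18875985 to 18876800; 61, 76 and 75 against 78, 120 and 120, 0.85, adjusted p = 9.94e-05), 48531 bp from Diras2 (19, 23 and 16 against 30, 36 and 41, 1.16) and inside Arhgap22 (21, 29 and 20 against 38, 39 and 35, 0.98). The fragments are unscaled and the folds scaled. Genes such as Arid5b and Cxcl2 were picked out after their values were seen. The smallest p belonged to chromosome 17, 39847574 to 39848713 (1058, 1194 and 1027 against 594, 632 and 809, −0.41), where mm10 carries a copy of the repeated ribosomal RNA genes, so that reads of many copies pile up.

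The other 9 splits of the libraries gave at most 1 region past this test, and only 1 of the 10 splits, the treatment split, gave 56; 10 splits are too few for a share under 0.05. At an unadjusted limma p under 0.05 the other splits gave 971 to 2155 regions, against 3339 in the treatment split. Fragment length as the whole cause was predicted to leave at most 1 region after regression on region width and height, and 41 of the 56 regions stayed past the threshold. A smooth trend with width and height thus did not account for most of them. Fragment lengths themselves were not entered, so fragment length is not excluded. The median width of called regions was 1023 bp for those lower and 721 bp for those higher in the siRNA-labelled libraries, against 799 bp for all regions tested. Coverage as the whole cause was predicted to leave at most 1 region after thinning all libraries to the lowest coverage. A median of 18 was left (SD 7.06, 3 to 27, and more than 5 in 18 of 20 draws). Thinning kept the summits and regions found at full coverage, so effects of coverage on finding them remain and coverage is not excluded. Thinning both groups alike, which keeps their coverage difference, left 10. Libraries of a group taken from 1 sample stay open, since the highest value within a group, 1.22 for siRNA-labelled libraries 1 and 2, can come from separate preparations of 1 sample as well. The count was 3, 9 and 7 without NC-labelled libraries 1, 2 and 3, 358, 7 and 43 without siRNA-labelled libraries 1, 2 and 3, and 12 with siRNA-labelled libraries 2 and 3 counted as 1 sample, so a change of Arid3a occupancy at these regions is a hypothesis that may not hold, untested against a preparation difference between the groups.

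The excess of NC-only (482) over siRNA-only regions (271) may come from coverage. After thinning to the lowest coverage and calling at a single p, the median ratio of the counts was 1.01 (0.940 to 1.06 over 20 draws), against 1.78 as deposited, which is what such a cause would give. Thinning matched the background only, and the siRNA-labelled lists were then the longer ones (48190 against 46392 peaks on average). Other settings kept the excess, with 407 NC-only against 240 siRNA-only regions at the same number of peaks in each list. With −log10 q of at least 5 the counts were 548 against 118. Neither setting matches the coverage of the libraries, so coverage as the cause stays undecided. Nearness to the calling threshold was not decided: 0.622% of the NC-only regions lay above percentile 50 of all 3 of their lists, but regions lacking in 3 lists are weak by selection, and the siRNA-only regions were weak too (3 of 271). The treatment split had the most one-sided regions (753, the highest other 633) and the most one-sided genes (57, the highest other 49), each in 1 of 10 splits, which are too few for a share under 0.05. Among the 57 genes, 8 NC-only and 1 siRNA-only had a peak of the other group in the same union region.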
